A study of Mus musculus with 9 samples.

How the data were processed

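RNA-seq was performed on 9 subcutaneous MC38 tumours grown in C57BL/6 mice. MC38 is a mouse colon adenocarcinoma cell line. The cells stably expressed a non-targeting control shRNA (NTC) or 1 of 2 shRNAs against Gad1 (shA and shB), with 3 libraries per group, and tumours were collected on day 20. Per the labels' protocols, cells were infected with lentivirus and selected with puromycin, total RNA was purified on columns, and libraries were made with a NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq. Whether each tumour came from its own mouse is not given in the sources used here, so p-values measure the spread between these libraries.

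The deposited values are a signal of one kind: read counts per gene divided by 1 factor per library. This was read from the values themselves, since the file headers name only the gene and a value. In each library 100% of the values were whole multiples of the smallest value above 0, within a tolerance of 0.001, and the factors equalled median-of-ratios size factors of the recovered counts. Per the submitters' processing notes, Cuffdiff 2.2.1 and the build mm9 were used, with no role stated. The values do not behave as FPKM, which depend on transcript length. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here, so overlapping genes and near-identical family members such as the haemoglobin and Rps genes are uncertain. In NTC replicate 2 the smallest value was 1.00, too close to a whole number for the formal check of recovered reads, although the same test on multiples held there.

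The design had anticipated FPKM or raw counts. As the unit was a normalized one, limma 3.58.1 in R 4.3.3 was the main test, on log2(value + 0.5), with a trended empirical Bayes prior and Benjamini-Hochberg adjustment. Fold changes are differences of mean log2 values on that scale. For low genes they depend on the added 0.5 and on single libraries at 0, and they can lie above or below the ratio of the group means. One model with 3 groups was fitted to all 9 libraries, and 4 comparisons were drawn from it. The comparison of both shRNAs versus NTC set the average of the shA and shB means against NTC. A gene called in it need not pass with each shRNA alone. The planned filter of 0.5 FPKM in 3 libraries was translated to 20 normalized reads in 3 libraries, and the planned mean of 1 FPKM for named genes to 40, for a transcript of 2 kb and 20000000 reads per library. This translation was made after the unit was seen and before any test was run. It left 14600 of 17134 listed genes.

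The comparisons, 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were Gad1; the 10 rising and 10 falling genes with the largest change against NTC for both shRNAs; the 5 in each direction for each other comparison; and up to 4 members of each list with the smallest p. The first kinds had to pass an adjusted p of 0.05, exceed the mean of 40 and have groups that did not overlap. Where none passed, 2 per direction with the smallest p were named and are stated as not passing. Predicted genes, immunoglobulin and T cell receptor segments, small RNAs and pseudogenes were left out of the ranked genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Of the 29 lists, 28 had at least 3 tested members. Gad1 was also tested by an exact two-sided permutation test.

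Alternatives covered the pseudocount, filter, scaling, empirical Bayes settings, library weights, groups in the fit, a replicate block, a fold threshold and each library left out. Chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, a filter of 0.5 normalized reads, the first replicate of each group left out together, and removal of a transcript length trend. Lengths came from a GRCm38 annotation and served only for trends, so no coordinates are given. No symbol occurred on more than 1 row.

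The test was checked on simulated counts with 200 changed genes, drawn from the real means, depths and dispersions. Genes were drawn independently and the library factors were taken as known, so deviations that many genes share were not covered. For both shRNAs versus NTC, with 14369 genes tested, 92.6% of genes changed by 4-fold and 56.0% of those changed by 2-fold were called, with 10 unchanged genes called. For shA versus shB, with 14337 genes tested, these shares were 83.8% and 33.0%. This check was run after the main test had first been run. Libraries held 18373748 to 24918174 assigned reads. Replicates differed by more than counting error, with a chi-square per degree of freedom of at least 8.05 between libraries of a group. A fold against a group at 0 was computed against a floor of 3 counts per library, which covers counting error only.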

Results

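Gene expression was measured in MC38 tumours whose cancer cells carried a control shRNA or 1 of 2 shRNAs against Gad1, which encodes glutamate decarboxylase, the enzyme that makes GABA from glutamate. Each of the 3 groups had 3 libraries, and the depth ranged from 18373748 reads in NTC replicate 1 to 24918174 in shA replicate 3. A whole tumour sample holds cancer cells together with host immune, stromal and vascular cells. The first principal component held 58.3% of the variance and separated NTC from the knockdown libraries. The comparisons ask what differs in tumours after Gad1 knockdown, and whether the shRNAs differ from each other.

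Gad1 was lower in all 6 knockdown libraries than in any NTC library. NTC tumours had 291 ± 31.8 normalized reads (SD, n = 3), shA tumours 28.8 ± 19.1 (SD, n = 3) and shB tumours 29.2 ± 11.3 (SD, n = 3). Single libraries read 281, 265 and 326 for NTC, 13.1, 23.4 and 50 for shA, and 21.8, 42.2 and 23.6 for shB. The log2 change for both shRNAs was -3.43 (SE 0.41), a 10.8-fold decrease, with an adjusted p of 0.000643 in limma. The exact permutation p was 0.0119 over 84 assignments. For each shRNA alone the exact p was 0.1, the smallest that 3 against 3 libraries allow, and for shA against shB it was 0.9.

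**Figure D1:**
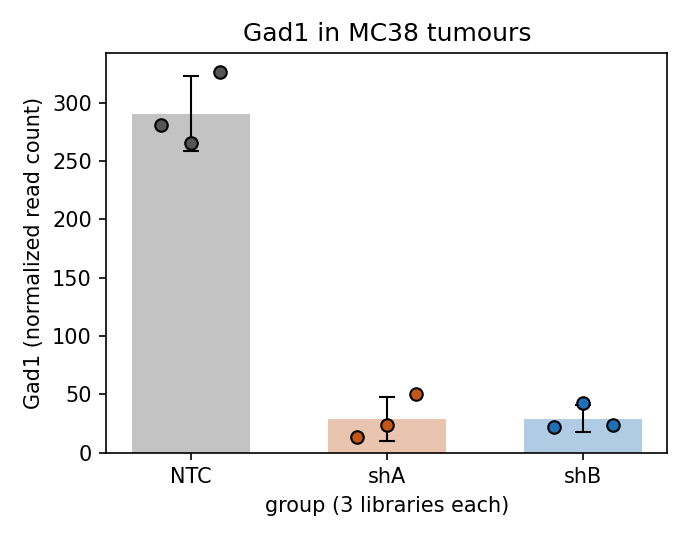
Normalized Gad1 read count by group. Points are libraries, bars are means of 3 libraries and error bars are SD. The NTC libraries sit between 265 and 326 and the knockdown libraries between 13.1 and 50.

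T cell genes were higher in the knockdown tumours. All 20 tested T cell markers rose when the average of both shRNAs was set against NTC, also when adjusted over the list alone. Their mean log2 change was 3.50. With each shRNA alone, 20 rose with shA and 17 with shB. Icos, a costimulatory receptor, rose 21.5-fold, Cd8b1, a chain of the CD8 co-receptor, 9.04-fold and Cd2 11.5-fold, with adjusted p of 0.000631, 0.000712 and 0.00105 in limma. Of 15 genes of cytotoxic lymphocytes, 13 rose, and the same number adjusted over the list alone. Nkg7, a granule membrane protein, went from 23.4 ± 25.6 in NTC to 329 ± 21.9 with shA and 224 ± 8.39 with shB (SD, n = 3). Gzma, a granule protease, rose 20.4-fold and Cxcr6, a chemokine receptor, 11.2-fold. All 12 tested genes of inhibitory receptors and regulatory T cells rose, also adjusted over the list alone, among them Lag3 by 4.71-fold and Entpd1 by 5.09-fold. Of 6 NK cell genes 5 rose, also adjusted over the list alone, including Klre1 by 5.93-fold. Without NTC replicate 1, which had the lowest immune scores, 18 T cell, 9 cytotoxic, 11 inhibitory and 3 NK cell genes rose, and the T cell mean was 2.83. The log2 changes of Icos and Nkg7 were then 3.69 and 3.21, and Gzma rose 12.1-fold. The T cell mean was 2.54 without the first replicate of each group. The camera adjusted p was 4.12e-12 for T cells, 6.48e-08 for cytotoxic lymphocytes, 9.71e-10 for inhibitory receptors and 0.00258 for NK cells. With an estimated correlation the adjusted p was 0.327 for the first 3 lists and 0.339 for NK cells.

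Myeloid genes were higher as well. Of 17 macrophage genes 15 rose, also adjusted over the list alone. C1qc, a complement component, went from 449 ± 193 in NTC to 4269 ± 862 with shA and 2889 ± 607 with shB (SD, n = 3), Apoe rose 4.82-fold and Lyz2, which encodes lysozyme, 6.12-fold. Of 14 dendritic cell genes 11 rose, and 12 adjusted over the list alone, including Itgax by 10.0-fold and Clec9a, a receptor of cross-presenting dendritic cells, by 14.0-fold. Of 11 neutrophil genes 3 rose, and 4 adjusted over the list alone; these were Hdc, Csf3r and Retnlg over all genes, and none passed without NTC replicate 1, whereas 5 rose without the first replicate of each group. Camera gave adjusted p of 9.74e-12 for macrophages, 7.29e-07 for dendritic cells and 0.107 for neutrophils. With an estimated correlation the adjusted p was 0.327 for both of the lists called. The rising genes with the largest change included Retnla, a product of alternatively activated macrophages, and the eosinophil-associated ribonuclease genes Ear2 and Rnase2a, with Ccl24, an eosinophil attractant. Ccl24 went from 9.24 ± 9.55 in NTC to 1073 ± 1435 with shA and 243 ± 159 with shB (SD, n = 3). Its shA mean rests largely on shA replicate 1, at 2729 normalized reads, against 192 and 298 in shA replicates 2 and 3. Rnase2a had 0 reads in all NTC libraries and was at least 151-fold higher in the knockdown mean, against a floor of 3 counts per library, and its adjusted p was 0.0558 in edgeR. Its mean rests largely on shA replicate 1, at 2569 normalized reads. Retnla read 21977 in shA replicate 1 against 386 and 502 in shA replicates 2 and 3. Ear2 read 3648 there against 264 and 458.

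Interferon-response genes and chemokines rose with the immune markers. Of 26 genes of the interferon-gamma response and antigen presentation 25 rose, and 26 adjusted over the list alone. The MHC class II genes H2-Aa and H2-Ab1 rose by 4.25 and 4.21 on the log2 scale, and Cd74, the invariant chain, 19.2-fold. All 19 genes of the type I interferon response rose, also adjusted over the list alone, including the transcription factor Irf7 by 7.96-fold. Ifit1 went from 140 ± 89.9 in NTC to 1357 ± 638 with shA and 2085 ± 511 with shB (SD, n = 3). Gbp2b, an interferon-induced GTPase, rose 67.9-fold. Of 18 leukocyte chemokines 15 rose, and 17 adjusted over the list alone, with Ccl8 at 18.8-fold and Cxcl16 at 4.89-fold. Without NTC replicate 1, whose interferon-gamma score was -1.79, 24 interferon-gamma genes rose with a list mean of 2.12, against 3.01 with all libraries, and 12 chemokines rose. The log2 changes of H2-Aa, H2-Ab1 and Cd74 were then 3.37, 3.38 and 3.38, those of Ifit1 and Ccl8 3.08 and 3.24, and Gbp2b, with 0 reads in that library, rose 24.5-fold. Camera adjusted p were 2.52e-13, 1.79e-12 and 7.48e-09 for the 3 lists. With an estimated correlation the adjusted p was 0.339 for the interferon-gamma list and 0.327 for the others.

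**Figure D2:**
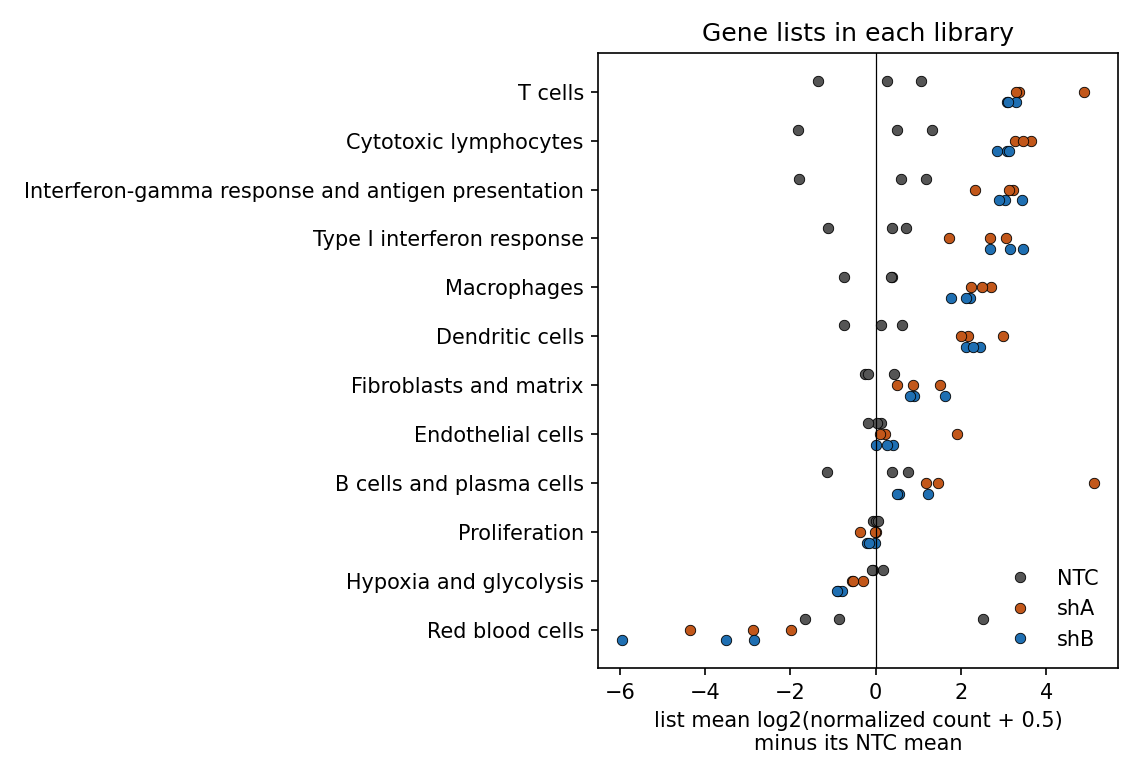
Mean log2 value of 12 gene lists in each library, relative to the NTC mean; each point is a library and colours give the group. T cell scores lie between 3.07 and 4.89 in the knockdown libraries and at most 1.06 in NTC, whereas B cell genes stand out in 1 shA library.

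The genes with the largest changes included several outside the lists. T (brachyury) and Pax7, developmental transcription factors, fell by 4.95 and 4.64 on the log2 scale. Brinp2 fell from 219 ± 76.5 normalized reads in NTC to 12.7 ± 8.28 with shA and 3.75 ± 2.28 with shB (SD, n = 3). Magel2 fell 21.8-fold and Trpa1, an ion channel, 14.7-fold. Slc6a7, a proline transporter, and Dkk4, a Wnt antagonist, fell 27.3-fold and 26.1-fold. Their adjusted p in limma were 0.0243 and 0.0252, against 0.0582 and 0.0553 with shA alone and 0.0475 and 0.0533 with shB alone. The calls for both shRNAs were lost without any one of the NTC libraries, with adjusted p up to 0.104 and 0.0888. The log2 changes then stayed between -5.11 and -4.42 for Slc6a7 and between -4.78 and -4.67 for Dkk4. Among rising genes were the sodium-proton exchangers Slc9a4 and Slc9a2, at 72.7-fold and 50.9-fold, the potassium channel gene Kcnc1 at 41.9-fold, C1qtnf3 at 60.0-fold and Gimap3 at 60.1-fold. NTC replicate 1 had 0 reads of Slc9a4, Slc9a2, C1qtnf3 and Gimap3, and without it they rose 42.2-fold, 27.1-fold, 28.5-fold and 18.3-fold.

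The Wnt target list moved in both directions. Of 20 genes 8 rose and 5 fell, and 8 and 7 adjusted over the list alone. Sox9, a transcription factor of intestinal progenitors, rose from 153 ± 36.3 in NTC to 999 ± 455 with shA and 2551 ± 724 with shB (SD, n = 3), and Myc rose 3.43-fold. Axin2, a negative regulator of the pathway and one of its targets, fell 1.59-fold and Tnfrsf19 1.91-fold. The list mean was 0.38, its median -0.03 and its camera adjusted p 0.885. Without NTC replicate 1, 4 genes rose and 3 fell. Of 17 genes of GABA and glutamate metabolism 2 rose and 5 fell, and 3 and 6 adjusted over the list alone. Gad1, the shRNA target, is in this list and among the falling genes, so part of that count was set by the design. Abat, which breaks GABA down, fell 8.25-fold and Gabbr1, a GABA-B receptor subunit, 1.58-fold, the latter with an adjusted p of 0.0816 in limma without NTC replicate 3 and 0.0653 without NTC replicate 1. Gabra3, a GABA-A receptor subunit, had 0 reads in NTC and was at least 5.81-fold higher in the knockdown mean against 3 counts per library. Without NTC replicate 1 the list had 1 rising and 2 falling genes, with Gad1 among the falling genes. Its camera adjusted p was 0.237.

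Hypoxia and glycolysis genes were lower. Of 18 genes 12 fell and none rose, and 12 fell and 1 rose adjusted over the list alone. The glucose transporter Slc2a1 fell from 12493 ± 3290 in NTC to 5146 ± 646 with shA and 3422 ± 582 with shB (SD, n = 3). Bnip3 fell 2.45-fold, Ero1l 2.27-fold and Hk2, a hexokinase, 1.68-fold. The camera adjusted p was 2.66e-07, and the adjusted p was 0.327 with an estimated correlation. Of 19 genes of the integrated stress response and amino acid supply 1 rose and 4 fell, with the same counts adjusted over the list alone; Slc7a11, a cystine transporter, fell 2.56-fold, and the camera adjusted p was 0.373. Of 26 proliferation genes none rose and 1, the replication helicase gene Mcm2, fell 1.37-fold; none passed adjusted over the list alone, and the camera adjusted p was 0.107. The Mcm2 call was lost when any 1 of 6 libraries was left out, all NTC libraries among them, with adjusted p up to 0.121. Without shB replicate 1, 3 proliferation genes rose and 6 fell, and without the first replicate of each group 4 rose and 10 fell. Oxidative phosphorylation (92 genes) and cytosolic ribosomal proteins (83 genes) had 1 falling gene each, Ndufa4l2 and Rps10, and 1 and 0 adjusted over the list alone, with camera adjusted p of 0.420 and 0.950. Without shB replicate 1, in which ribosomal genes took 5.33% of reads, 30 oxidative phosphorylation genes rose and 2 ribosomal genes rose. Both lists then passed as higher by camera, with adjusted p of 8.99e-06 and 0.00824. The Rps10 call was lost without NTC replicate 1 or 3, with adjusted p of 0.0852 and 0.0606.

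Other cell types differed less evenly. Of 18 fibroblast and matrix genes 9 rose and 1 fell, and 10 and 1 adjusted over the list alone; Mmp2, a matrix metalloproteinase, rose 3.61-fold and Dcn, a matrix proteoglycan, 8.14-fold. The camera adjusted p was 0.000867, and the adjusted p was 0.441 with an estimated correlation. None of 15 endothelial genes passed in limma, also adjusted over the list alone, with a camera adjusted p of 0.107; Pecam1 had 726 ± 122 in NTC, 2009 ± 1892 with shA and 952 ± 140 with shB (SD, n = 3). Without shA replicate 1, 2 endothelial genes rose. Of 13 epithelial and tumour cell genes 3 rose, among them Cdh1, E-cadherin, by 1.49-fold and Krt7 by 4.02-fold, and 1, Cdx2, fell; 7 rose and 1 fell adjusted over the list alone, with a camera adjusted p of 0.0506. Without shB replicate 1, 8 epithelial genes rose with a camera adjusted p of 0.00948, and without NTC replicate 1 the camera adjusted p was 0.0237. The Cdx2 call was lost without any one of the NTC libraries and without shB replicate 2 or 3, with adjusted p up to 0.132. With all libraries the epithelial list had an adjusted p of 0.579 with an estimated correlation. Of 6 adipocyte genes 4 rose, also adjusted over the list alone, including the lipases Pnpla2, Lpl and Lipe. The camera adjusted p was 0.00462, and the adjusted p was 0.366 with an estimated correlation. The Lipe call was lost without NTC replicate 1 (adjusted p 0.0693). Only 7 of the 15 adipocyte genes listed had values, so no conclusion on adipocyte content is drawn. Of 5 skin keratinocyte genes 1, Lor, rose, and 3 adjusted over the list alone, with a camera adjusted p of 0.175. Of 17 immediate early genes 3 rose, Egr2 by 4.93-fold, Zfp36 and Junb, with a camera adjusted p of 0.217. The Junb call was lost when any 1 of 7 libraries was left out, all NTC libraries among them, and that of Zfp36 without NTC replicate 1 or 2, with adjusted p up to 0.103 and 0.0836. Without NTC replicate 1, 1 immediate early gene rose, and without the first replicate of each group 7 did; without shB replicate 1 the camera adjusted p was 0.0367. Of 16 heat shock genes 2 rose, Bag3 by 1.81-fold and Hspb1 by 3.58-fold, with a camera adjusted p of 0.102. Without shB replicate 1, 4 heat shock genes rose with a camera adjusted p of 0.0336, without NTC replicate 1 that p was 0.0161, and without the first replicate of each group 9 rose. With all libraries the adjusted p was 0.745 for immediate early and 0.619 for heat shock genes with an estimated correlation. These 2 lists had the same counts adjusted over the list alone.

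Several lists had single libraries far from the rest. Red blood cell genes fell in 4 of 5 cases, and 5 adjusted over the list alone. Hbb-bs, a beta globin, read 35335 in NTC replicate 1 against 3815 and 2009 in the other NTC libraries, and Alas2 2300 against 150 and 65.3; haemoglobin took 0.284% of reads in that library. Without it no red blood cell gene passed, and Hbb-bs had a log2 change of -2.53 and an adjusted p of 0.0749 in limma, whereas the list mean was -2.32 with a camera adjusted p of 0.00864. Without the first replicate of each group all 5 genes fell. The camera adjusted p of the list was 0.00519, and the adjusted p was 0.441 with an estimated correlation. Of 12 skeletal muscle genes 1, Casq1, rose, and none adjusted over the list alone. The Casq1 call was lost without any one of the NTC libraries and without shA replicate 2 or 3. The list score was 5.74 in shB replicate 1, and 3.86, 3.04 and 3.61 in shA replicates 2 and 3 and shB replicate 3. In shA replicate 1 and shB replicate 2 the list score was -0.06 and -0.25. The camera adjusted p of the muscle list, 0.0464, became 0.126 without shB replicate 1, 0.0671 without NTC replicate 1 and 0.0139 without shA replicate 1. With an estimated correlation the adjusted p was 0.643. Mitochondrially encoded RNAs took 6.60% of reads in shA replicate 1 and 0.491% to 1.49% elsewhere; 2 of 18, mt-Nd6 and mt-Rnr2, rose, and none adjusted over the list alone. The list score was 4.11 in that library, 0.84 to 1.41 in the other knockdown libraries and at most 0.36 in NTC. Both calls were lost without any one of the NTC libraries and without shB replicate 2 or 3, with adjusted p up to 0.124 for mt-Nd6 and 0.178 for mt-Rnr2. That of mt-Rnr2 was also lost without shB replicate 1 (adjusted p 0.0563). Without shA replicate 1, 12 rose, with a list mean of 1.07 and a camera adjusted p of 2.40e-07. By camera the adjusted p of this list was 0.000302, and the adjusted p was 0.579 with an estimated correlation. B cell and plasma cell genes had 1 riser of 3, Jchain, also adjusted over the list alone, with a camera adjusted p of 0.323. Xist, the only tested sex-linked gene, had a log2 change of 1.68 (SE 0.52) and an adjusted p of 0.0412 in limma. The Xist call was lost without any one of the NTC libraries and without shA replicate 1 or 2. Its adjusted p was highest, at 0.181, without NTC replicate 1.

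In total 3644 of 14600 genes changed in limma when the average of both shRNAs was set against NTC, 2258 rising and 1386 falling. Genes called with shA and also with shB were fewer, 1408 rising and 541 falling. With quantile normalization the averaged comparison gave 1815 rising and 1831 falling genes, so its share of rising genes went from 62.0% to 49.8%. The count was 2005 without NTC replicate 1, 2352 without NTC replicate 3 and 5498 without shB replicate 1. Control and knockdown cells were separately infected and selected, so a difference between the cell populations that preceded the tumours cannot be separated from the knockdown here.

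With shA against NTC, 2478 genes changed, 1662 rising and 816 falling. The strongest risers were Retnla, Rnase2a, Ccl24, Gimap3 and Gbp2b, and the strongest falls were those of T (brachyury), Pax7, Brinp2, Magel2 and Trpa1. Of the risers, all but Gbp2b were far higher in shA replicate 1 than in shA replicates 2 and 3, with Gimap3 at 1229 against 246 and 249. Trpa1 fell 11.9-fold. All 20 T cell genes and 19 type I interferon genes rose, and 7 of 18 hypoxia genes fell. For these lists camera gave adjusted p of 4.93e-13, 3.19e-11 and 7.42e-05, and the adjusted p was 0.308 with an estimated correlation for each. With shB against NTC, 2983 genes changed, 1958 rising and 1025 falling. Retnla, C1qtnf3, Slc9a4, Slc9a2 and Rnase2a led the risers, and Brinp2, Magel2, Slc6a7, Pax7 and Hbb-bt the falling genes. Here 17 of 20 T cell genes and all 19 type I interferon genes rose, 12 of 18 hypoxia genes fell and 1 rose. Here camera gave adjusted p of 3.16e-10, 1.30e-13 and 2.52e-09, and the adjusted p were 0.367, 0.334 and 0.190 with an estimated correlation. Quantile normalization took the rising share from 67.1% to 53.8% for shA and from 65.6% to 53.9% for shB. The shA count was 1268, 1576 and 1552 without NTC replicates 1, 2 and 3 and 3992 without shB replicate 1; the shB count was 1835 without NTC replicate 1, 1859 without shB replicate 2 and 1895 without shB replicate 3.

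The changes with the shRNAs ran in the same direction. Genes called with shA and also with shB numbered 1408 rising and 541 falling, with 0 in opposite directions. Independent lists of these sizes would share 223 and 57.3 genes. Across genes, which are not independent replicates, the correlation of the log2 changes was 0.904, against 0.501 on average in 50 simulations of unchanged groups sharing the NTC libraries. The covariance was 1.00 against a simulated 0.0719. The simulations drew noise for each gene independently. In the data, genes of a list moved together, with an estimated correlation of 0.73 for T cell and 0.82 for interferon-gamma genes. The simulations therefore do not cover deviations that many genes of an NTC library share, and no conclusion is drawn from them. The 3 controls cannot be divided so that each shRNA keeps 2 of its own, so the shared controls contribute to the correlation and to the shared calls. Genes called in both numbered 1080 without NTC replicate 1 and 2989 without shB replicate 1.

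**Figure D3:**
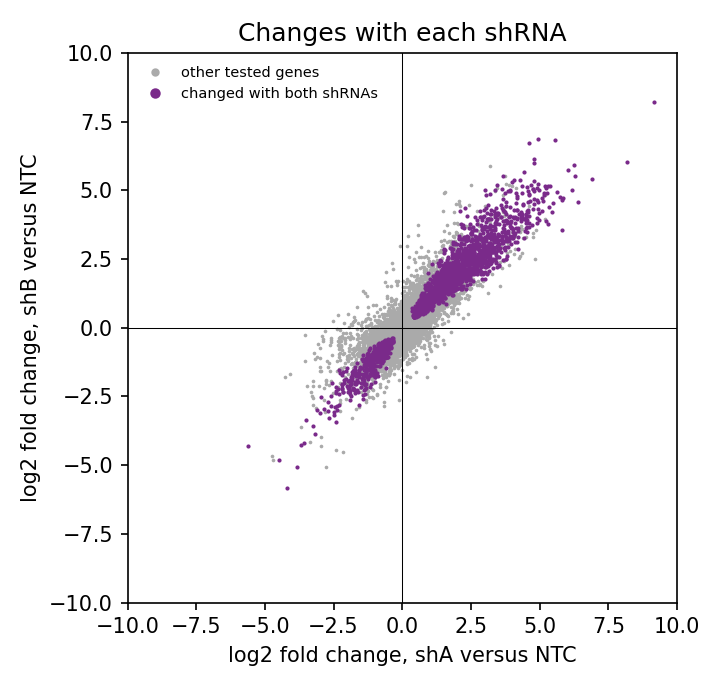
Log2 fold change of each tested gene with shA (x axis) and shB (y axis) against NTC. Purple points are the genes called with shA and also with shB, 1408 rising and 541 falling, and grey points are the other tested genes.

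No gene differed between shA and shB in limma, with 1010 of 14600 genes at an unadjusted p under 0.05; edgeR called 0 and DESeq2 24. Genes with the smallest p did not pass. Uox, urate oxidase, read 700 ± 157 with shA and 241 ± 85.1 with shB (SD, n = 3), and Fgfbp3 2557 ± 598 and 1151 ± 205. Dennd4a read 588 ± 38.0 with shA and 912 ± 20.2 with shB, and Pclo 93.2 ± 42.8 and 297 ± 20.0 (SD, n = 3). Each had an adjusted p of 0.680 in limma. Hypoxia genes were on average 0.40 higher on the log2 scale with shA, with 0 of 18 genes called over all genes and 6 adjusted over the list alone. The camera adjusted p was 8.60e-09, and the adjusted p was 0.203 with an estimated correlation. Leaving out the first replicate of each group gave 13 genes, and leaving out shA replicate 3 gave 1.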

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

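All tests of explanations in this part were chosen after the results were seen. For transcript length only, the prediction was written before the outcome of its own test was known. The lists below differed between shA and shB when their change against NTC was compared directly, by camera with a preset correlation; none did with an estimated correlation, where the lowest adjusted p was 0.203. Higher with shA were hypoxia and glycolysis (adjusted p 8.60e-09), the integrated stress response (0.000887), oxidative phosphorylation (3.38e-12), cytosolic ribosomal proteins (5.88e-15), macrophages (0.000887), T cells (0.00185), endothelial cells (0.00458) and mitochondrially encoded RNAs (0.00536). Lower with shA were type I interferon genes (0.000336) and Wnt targets (0.00536). Without the first replicate of each group, hypoxia, the stress response and macrophages stayed higher and type I interferon genes lower with shA by camera. T cells, Wnt targets, endothelial cells and oxidative phosphorylation no longer passed, with mean log2 differences of 0.25, -0.24, 0.02 and -0.02 and adjusted p of 0.167, 0.159, 0.856 and 0.178. With all libraries these differences had been 0.69, -0.33, 0.51 and 0.40. Ribosomal genes and mitochondrially encoded RNAs turned, with mean log2 differences of -0.06 and -0.35 and adjusted p of 0.0346 and 0.0016. In this setting proliferation (8.48e-08), cytotoxic (0.0173) and muscle genes (0.0207) were higher and epithelial (9.25e-07) and immediate early genes (4.38e-06) lower with shA, although not with all libraries. With an estimated correlation no list differed here either, with a lowest adjusted p of 0.227.

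Of 70 rising members of 4 immune and interferon lists, 68 still rose without the first replicate of each group. These members were picked as rising in the same libraries, so this count cannot decide by itself. Over all tested members, 20 of 20 T cell, 13 of 15 cytotoxic, 11 of 12 inhibitory receptor and 26 of 26 interferon-gamma genes rose in that setting. This argues against the libraries that stood apart as the whole cause. The list means were smaller there, at 2.54 for T cells, 2.36 for cytotoxic and 2.28 for interferon-gamma genes against 3.50, 3.24 and 3.01 with all libraries, so these libraries carried part of the size. The T cell list mean was at least 2.79 on the log2 scale under 3 other scalings, against the scaling as the cause. A lower share of cancer cells would raise markers of every other cell type alike, if cancer cells express none of them. The T cell score exceeded the endothelial score by more than in any NTC library in all 6 knockdown libraries. That comparison restated list values already seen, so its outcome was known beforehand. List means were 3.50 for T cell, 2.26 for macrophage, 1.03 for fibroblast and 0.48 for endothelial genes. Such uneven rises go against a lower share of cancer cells as the whole cause only if cancer cells express none of these markers. That condition was not tested, and the list means are values already seen. A change in the immune cells present with the knockdown, and a difference between the separately selected cell populations, both stay open and untested.

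B cell genes were high in shA replicate 1, with Cd79a at 991 normalized reads and at most 36.5 elsewhere. No explanation was tested.

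By genes called over all genes, the knockdown libraries did not divide by shRNA. That count can miss differences, since the simulated check recovered 33.0% of 2-fold changes for shA versus shB. Some list scores did divide: hypoxia scores were -0.56 to -0.29 with shA and -0.90 to -0.80 with shB. T cell scores overlapped, at 3.29 to 4.89 with shA and 3.07 to 3.30 with shB. The split that exchanged shA replicate 3 and shB replicate 1 called 23 genes, against 0 for the real groups. With the transcript length trend removed it called 39, against length as the cause. Leaving the pair itself aside, 1 of the 2, shA replicate 3, correlated better with each remaining library of the other shRNA than with its own. The other did so with shA replicate 2 but not with shA replicate 1, which stood apart from all, so an exchange cannot be told apart from ordinary variation between tumours; reading this value as open was decided after it was seen.

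For both shRNAs versus NTC, 2 of 100 splits of the 9 libraries gave as many genes as the real 3644, a share under 0.05; the highest other, 3663, kept the 3 NTC libraries together, and the highest that moved an NTC library gave 105. With 10 splits a share under 0.05 cannot be reached for the other comparisons. The real grouping, 1 of 10 splits as large, gave 2478 genes for shA versus NTC and 2983 for shB versus NTC, against 0 in the highest other split of each. For shA versus shB all 10 splits gave at least the real 0, and the highest other gave 23.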

How the results depend on the processing

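Chosen after seeing the data were edgeR, DESeq2, the filter of 0.5 normalized reads, the first replicates left out together and the length trend removed. For both shRNAs versus NTC, no called list and no called gene among the named genes changed direction. Other called genes were not followed 1 by 1. The means of 3 lists not called in the main test crossed 0 under some alternatives (ribosomal, oxidative phosphorylation and GABA genes), as did named genes that did not pass. For shA versus shB, the ribosomal and mitochondrially encoded lists turned without the first replicates. Under quantile normalization, rising genes were no longer the majority of the genes called for both shRNAs versus NTC (49.8% rising). Gad1 kept its call throughout, from -4.01 (shA, without shA replicate 3) to -2.78 (shB, library weights). The replicate numbers did not pair the samples, since 0 of 9 same-numbered pairs had deviations correlated above 0.1 (-0.34 to 0.06); with them as a block the counts were 2921 (both), 1778 (shA), 2376 (shB) and 0 (shA versus shB). Symbols on more than 1 row were not left out, as none exist, and the filter of 0.5 normalized reads kept the same genes as no filter.

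A 2-fold threshold gave 2098 genes for both and 1984 for shB. Library weights gave 8819, 6063, 9847 and 1396 genes for both, shA, shB and shA versus shB. They gave 5709 genes called with shA and also with shB. However, the weight estimate stopped before converging and gave shB replicate 2 a weight of 22.3. Without the first replicates the counts were 6361, 3930, 6526 and 13, with 3632 genes shared. DESeq2 called 24 genes for shA versus shB. Leaving out single libraries gave 2005 to 5498 genes for both, 1268 to 3992 for shA, 1835 to 4237 for shB, 0 to 1 for shA versus shB, and 1080 to 2989 shared. The cause was not tested.

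Camera called 15 of 28 lists, 0 with an estimated correlation, 12 with fry. By fry the adjusted p was 0.00461 for T cells, 0.00122 for macrophages and 0.000962 for hypoxia genes. Of the lists called by camera, fry did not call muscle (0.222), mitochondrially encoded (0.140) and red blood cell genes (0.0542). Epithelial genes passed with mean log2 changes of 0.64 (DESeq2), 0.52 (median centring), 0.53 (equal totals), 0.56 (no filter, filter 0.5, pseudocount 0.1 and the replicate block), 0.53 (filter of 80 reads), 0.43 (quantile normalization) and 0.83 (without first replicates). Muscle genes no longer passed at 2.74 (80 reads), 2.196 (without first replicates), 1.97 (quantile), 2.66 (replicate block) and 2.63 (length trend removed). With 80 reads neutrophils (1.84) and keratinocytes (1.01) passed; with quantile normalization heat shock genes (0.18). Without the first replicates fibroblast genes no longer passed (0.64), whereas ribosomal (0.13), heat shock (0.44), immediate early (0.66), oxidative phosphorylation (0.16) and proliferation genes (-0.13) did. Over single libraries left out, means ran from 0.43 to 0.73 for epithelial, 1.98 to 3.48 for muscle, 0.19 to 0.64 for endothelial, 0.17 to 0.38 for heat shock and 0.28 to 0.55 for immediate early genes. They ran from -0.163 to -0.0672 for proliferation, -0.0077 to 0.26 for oxidative phosphorylation and -0.0742 to 0.20 for ribosomal genes. Of the comparisons of named genes with an alternative, 3200 kept their side of the threshold, 97 lost and 108 gained the call. Whether depth limits genes near 20 reads was not tested.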
